A study of Homo sapiens with 12 samples.

How the data were processed

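ERα ChIP-seq was carried out in MCF7 and T47D breast cancer cells and in Ishikawa and ECC1 uterine cancer cells, each with 100 nM E2 or ethanol for 45 min. Per the labels' protocols, chromatin was cross-linked with formaldehyde, sonicated to about 500 bp, precipitated with an ERα antibody and sequenced on an Illumina Genome Analyzer from inserts of 150 to 300 bp. The 12 samples comprised 8 ChIP libraries, 1 per line and treatment, and 4 input libraries, 1 per line. The input libraries were not analysed here and enter no comparison.

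The deposited file of each ChIP library was a list with a chromosome, a single position and a whole-number score per peak, without a header. What the score measures, how it was scaled and which peak caller and threshold were used is not stated in the labels or the files, and the authors' score was used to describe, rank or filter peaks within a list. The only exceptions were alternatives that apply one lowest score to several lists, the lowest ethanol score of a line or 14 in all lists, which take scores as comparable between lists, an assumption that could not be checked. The submitters' processing notes name the genome build hg18, and the deposited positions, which are the other column used, were read as hg18 positions counted from 1. The lowest score was 9 in the 4 E2 lists, 14 in both breast ethanol lists and 11 in both uterine ethanol lists. Lists thus differed in filtering or in scaling of the score, which cannot be told apart. Positions had also been set jointly within a tissue: of 7870 matches within 250 bp among the 12 pairs of lists of the same tissue, 0 were 1 to 250 bp apart, against 2659 of 3046 matches among the 16 pairs from different tissues. Sharing within a tissue was thus counted between identical positions and sharing between tissues mostly between close ones. The labels state 7 to 12 M unique tags per ChIP library. The lists hold no read counts, so the depth behind a single library or peak is unknown, and all intervals cover the counting of peaks only.

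Treatment and line were taken from the titles. In 1 T47D library titled E2 the description and agent label say ethanol, and in 1 Ishikawa library titled ethanol they say E2; the titles alone give each line both treatments, as the series design states. The source label of the Ishikawa and ECC1 libraries calls the cells breast cancer cells, whereas the growth protocol calls them uterine, and the series design counts them as uterus. The latter was followed.

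A comparison by overlapping intervals had been fixed before the data were examined. Since the lists hold points and no intervals, 2 peaks counted as shared when their positions lay within 250 bp, which had been fixed as an alternative. Overlaps were set beside 1000 random placements of the shorter list on the same chromosomes and beside shifts by 20 to 200 kb. Proportions have exact Clopper-Pearson 95% intervals, and ratios of peak numbers have 95% intervals from the 2 numbers of peaks. Regions joined positions of the 4 E2 lists within 250 bp, and their numbers per combination of lines were set beside 1000 independent draws that kept each list's length. Scores of 2 sets of peaks within a list were compared by the difference of medians with 100000 permutations. Shares per chromosome and per band, for the 613 bands with at least 10 E2 peaks, were compared by Fisher's exact test, each list against the other 3, adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and the 4 lists over 23 chromosomes by a chi-square statistic with 100000 permutations. All tests were two-sided, apart from the random placements, which ask for more sharing, and the split of the lines into pairs, which asks for more sharing within tissues. Peaks are not replicates, so these tests describe the lists and not the conditions. Bands were taken from the hg18 cytoband table of circlize 0.4.16 in R 4.3.3. The rest was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The overlap count was tested on simulated data: of 1000 peaks, planted overlaps of 0, 200, 500 and 900 with the MCF7 E2 list were counted as 3, 203, 501 and 902. Among 40 simulations without a difference the median test made 0% and the chromosome test 5% false calls.

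The regions named were fixed by a rule before the data were examined. It takes the 8 regions of all 4 E2 lists with the highest mean percentile, the 5 highest by MCF7 score in both breast lines and neither uterine line, the 5 highest by ECC1 score in both uterine lines and neither breast line, the 5 regions of all 4 ethanol lists with the highest mean percentile, the 3 highest of each E2 list found in no other, and up to 3 chromosomes and 3 bands per list by odds ratio. Regions named outside this rule are said to be chosen after their values were seen. Alternatives were another distance (100 or 500 bp), the peaks of each list from its median score up, lists of equal length, a common lowest score of 14, E2 peaks from the lowest ethanol score, merging within 1 kb, 1 Mb windows, leaving out lines and leaving out sites like background. Distances to genes, motif searches and gene lists were left out because hg18 annotation and sequence were not used here. Comparisons by fold enrichment, p-value or peak width were left out because the lists hold none.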

Results

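Sites bound by oestrogen receptor alpha (ERα), a hormone-activated transcription factor, were measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in 4 human cancer cell lines. MCF7 and T47D are ERα-positive breast cancer lines, and Ishikawa and ECC1 were grown as uterine cancer lines. Cells were kept for 3 days in hormone-depleted medium and then given 100 nM oestradiol (E2), the natural ligand of the receptor, or its solvent ethanol for 45 min. There was 1 library for each line and treatment, hence no replicate error for any list, and every p-value or interval below compares lists of peaks and covers counting only. The labels put 7 to 12 M unique tags (M, 10 to the power 6) behind each ChIP library, without a value per library. In 1 T47D and 1 Ishikawa library the agent label contradicted the title, and the titles were followed, so directions between E2 and ethanol in these 2 lines rest on the titles. Each list gave positions on the hg18 build with the authors' score per peak. No peak was assigned to a gene because hg18 annotation was not used here, and regions are named by position and chromosome band.

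The first comparison asked how E2 changed the number of listed ERα sites in each line. MCF7 had 17442 peaks with E2 and 1250 with ethanol, a ratio of 13.95 (95% interval 13.2 to 14.8, counting error only). T47D had 5421 and 558 peaks, a ratio of 9.715 (8.90 to 10.6). The uterine lines had shorter lists, with 1096 and 192 peaks in Ishikawa (ratio 5.71, 4.89 to 6.69) and 1192 and 211 in ECC1 (ratio 5.65, 4.88 to 6.57). The E2 list was the longer one in 4 of 4 lines, and the mean log2 ratio was 3.02 ± 0.63 (SD, n = 4 lines; two-sided exact sign-flip permutation test, p = 0.12, the smallest that 4 lines allow). The lowest score was 9 in the E2 lists but 14 in the breast and 11 in the uterine ethanol lists. Counting E2 peaks only from the lowest ethanol score of the same line lowered the ratios to 8.83 in MCF7, 5.11 in T47D, 3.37 in Ishikawa and 4.12 in ECC1. Both this count and the next take scores as comparable between lists, which their unstated scaling leaves unknown. Counted from a score of 14 in all lists, the ratio was 4.67 in Ishikawa (3.72 to 5.90) and 5.46 in ECC1 (4.44 to 6.76); it stayed at 5.11 in T47D (4.66 to 5.61).

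**Figure D1:**
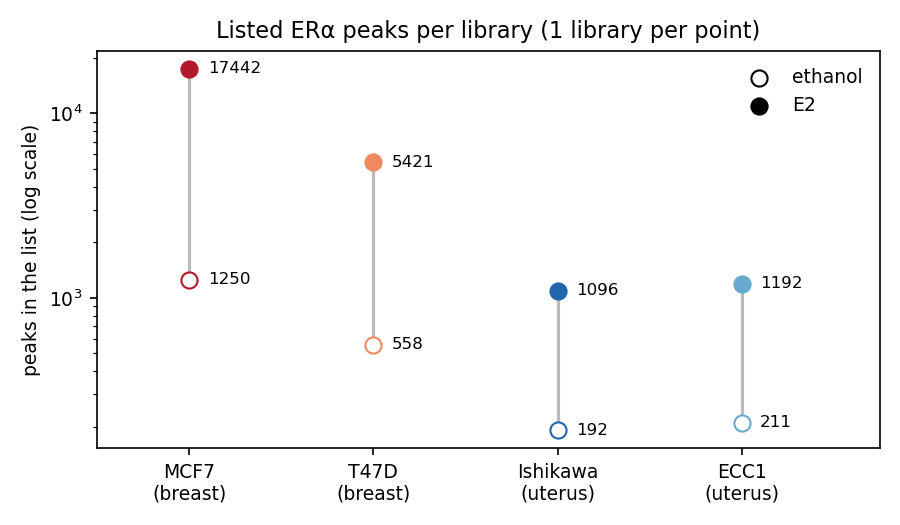
Number of listed ERα peaks (log axis) in each of the 8 ChIP libraries, with ethanol as open and E2 as filled circles and 1 library per circle. The E2 list was longer in all 4 lines, from 1096 peaks in Ishikawa to 17442 in MCF7.

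Most sites listed without hormone in the breast lines were listed again with E2. In MCF7, 1140 of 1250 ethanol peaks (91.2%, exact Clopper-Pearson 95% interval 89.5 to 92.7%) had an E2 peak within 250 bp, and in T47D 454 of 558 did (81.4%, 77.9 to 84.5%). In the uterine lines the share was 58.3% in Ishikawa (112 of 192, 51.0 to 65.4%) and 58.8% in ECC1 (124 of 211, 51.8 to 65.5%). Random placement on the same chromosomes gave means of 4.12 matches in MCF7, 0.608 in T47D, 0.039 in Ishikawa and 0.052 in ECC1, and none of 1000 placements reached the observed number in any line (permutation p = 0.001, the smallest they can give). Shifting the peaks by 20 to 200 kb, which keeps them in the same neighbourhoods, gave means of 9.77, 1.94, 0.171 and 0.132 matches. With E2 peaks counted only from the lowest ethanol score, the share fell to 39.1% in Ishikawa and 46.0% in ECC1. Seen from the E2 lists, 6.54% of MCF7, 8.38% of T47D, 10.2% of Ishikawa and 10.4% of ECC1 peaks had an ethanol counterpart.

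The E2 peaks that also had an ethanol peak were the high-scoring ones in the breast lines. Their median score was 110 against 16 for the other E2 peaks in MCF7 and 75.5 against 13 in T47D (two-sided permutation test over peaks, p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 1.33e-05 by the Benjamini-Hochberg method over 8 tests). The medians were 13 and 11 in Ishikawa (permutation p = 0.0854, adjusted p = 0.0976) and 13.5 and 13 in ECC1 (p = 1, adjusted p = 1), so no difference was detected in either uterine line. The highest-scoring MCF7 ethanol peak lay at 21q22.3 (chromosome 21, position 42669675, score 241), a band that holds TFF1, a textbook oestrogen-induced gene, and it was in both breast E2 lists and neither uterine one. The highest-scoring T47D ethanol peak lay at 12q24.22 (position 115312813, score 210) and was in all 4 E2 lists. The highest Ishikawa ethanol peak, at 1p22.2 (position 91625552, score 108), was in 3 ethanol and 3 E2 lists, and the highest ECC1 ethanol peak, at 2q21.2 (position 132743363, score 75), in 2 and 2. These 4 peaks were chosen after their values were seen, and without input libraries a high ethanol score does not by itself show receptor binding.

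Ethanol lists were compared with one another in the same way. The breast lines shared 326 regions (58.4% of the T47D list, 54.2 to 62.55%) and the uterine lines 93 (48.4% of the Ishikawa list, 41.2 to 55.7%). Pairs from different tissues shared 43 to 49 peaks, 20.4 to 24.0% of the shorter list. In all 4 ethanol lists 24 regions were present. The 5 with the highest mean percentile of score lay at 14q31.3 (chromosome 14, 87307450 to 87307461), 12p12.2 (chromosome 12, 20595686), 16p11.2 (chromosome 16, 33870743), 20p11.1 (chromosome 20, 26138025 to 26138036) and 1q22 (chromosome 1, 154453032 to 154453070). At 14q31.3 the ethanol scores were 93 in MCF7, 35 in T47D, 50 in Ishikawa and 60 in ECC1. Of the 24 regions, 4 lay within 2 Mb of a centromere. Those also in an E2 list had median percentiles there from 42.2 in T47D to 69.5 in Ishikawa. Input libraries were not analysed, so presence in all 4 ethanol lists does not show receptor binding, and background signal is possible.

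The series design asked which ERα sites the breast and uterine lines had in common and which were distinctive. After E2, MCF7 and T47D shared 3597 sites, 66.4% of the T47D list (65.1 to 67.6%). Ishikawa and ECC1 shared 567 sites, 51.7% of the Ishikawa list (48.7 to 54.7%). MCF7 held 520 Ishikawa sites (47.4%, 44.45 to 50.45%) and 649 ECC1 sites (54.4%, 51.6 to 57.3%). T47D held 378 Ishikawa sites (34.5%, 31.7 to 37.4%) and 415 ECC1 sites (34.8%, 32.1 to 37.6%). Random placement gave at most a mean of 17.5 matches, for MCF7 and T47D, and a permutation p = 0.001 for each of the 6 pairs, the smallest possible. Shifts by 20 to 200 kb gave a higher mean of 40.2 matches (at most 61) for that pair, and means of 1.08 to 9.17 for the others.

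The E2 lists ranged from 1096 to 17442 peaks, so the 1096 highest-scoring peaks of each list were also compared. This kept the whole Ishikawa list and most of the 1192 ECC1 peaks, but only the top-scoring part of the breast lists. Equal number is thus not equal stringency, and the cut removes breast sites that could match uterine ones. At that equal length, Ishikawa and ECC1 shared 540 sites (49.3%, 46.3 to 52.3%) and MCF7 and T47D 485 (44.3%, 41.3 to 47.25%). The 4 pairs from different tissues shared 174 to 204 sites (15.9 to 18.6%). The mean Jaccard index, the shared part of the union, was 0.306 within tissues (0.284 and 0.327) and 0.0913 between tissues (0.0862 to 0.103), a difference of 0.214. The 4 lines can be split into pairs in 3 ways only, so the exact permutation p was 0.333, the smallest possible, and no test at 0.05 could be made. The highest of the other splits gave -0.102. Positions had been set jointly within each tissue, so the split by tissue is also a split by this processing.

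High-scoring sites were found more often in the other lists. Of the lowest quintile of T47D E2 peaks by score, 33.2% were in the MCF7 list, and of the highest quintile 93.9% were. The corresponding shares of MCF7 peaks in the ECC1 list were 1.18% and 10.95%, and of Ishikawa peaks in the MCF7 list 26.4% and 66.2%. Of the 100 highest-scoring T47D peaks 99 were in the MCF7 list, against 72 of the Ishikawa and 78 of the ECC1 ones. In the other direction, 88 of the 100 highest MCF7 peaks were in the T47D list, 34 in Ishikawa and 39 in ECC1. E2 peaks shared with the other tissue had a median score of 54 against 17 for the rest in MCF7, 29 against 13 in T47D, 14 against 10 in Ishikawa and 15 against 12 in ECC1 (permutation p = 1e-05 and adjusted p = 1.33e-05 in each).

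**Figure D2:**
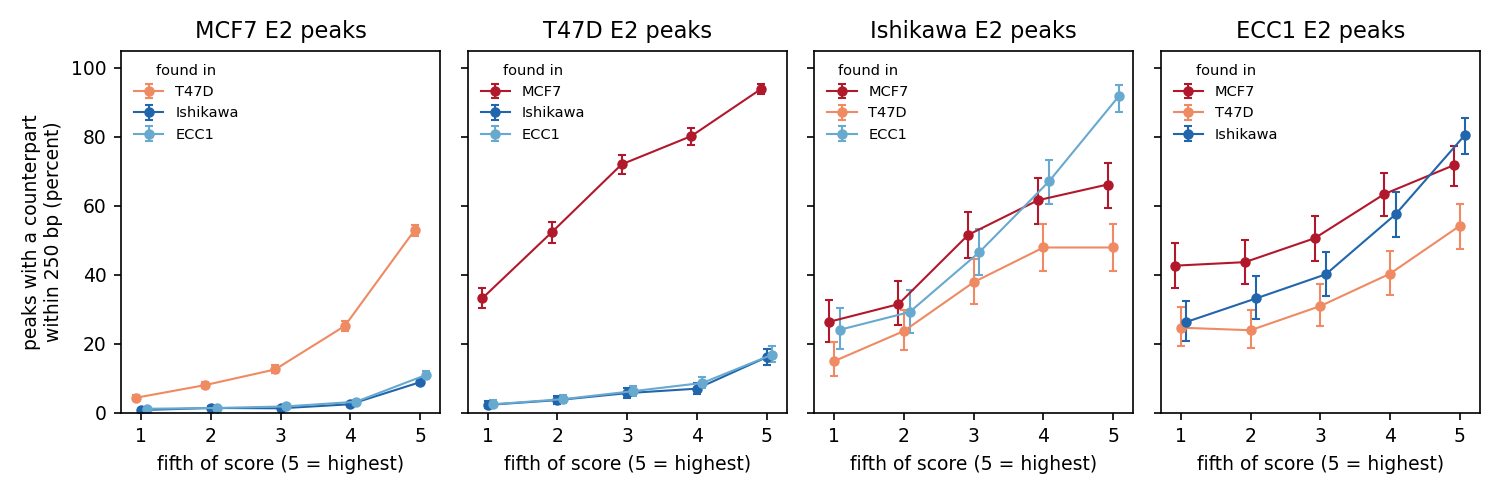
Share of the E2 peaks of each line with a counterpart within 250 bp in another E2 list (percent, bars are exact 95% intervals), by quintile (5 the highest) of the authors' score within the list. The share of T47D peaks found in MCF7 rose from 33.2% to 93.9%, and that of MCF7 peaks found in ECC1 from 1.18% to 10.95%.

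Joining positions within 250 bp gave 20144 regions over the 4 E2 lists. One line alone accounted for 16000 regions, of which 13527 were MCF7 regions, and 3537, 351 and 256 regions lay in 2, 3 and 4 lines. Both breast lines and neither uterine line held 3104 regions, and both uterine lines and neither breast line held 197. If the 4 lists drew independently from these regions, a mean of 6.33 (at most 15 in 1000 draws) would lie in both uterine lines alone and 15.1 (at most 27) in all 4. The same draws gave a mean of 4175 for both breast lines alone, above the observed 3104. For regions in any breast and any uterine list they gave 2005, above the observed 843. The draws use only regions that some list holds, most of them MCF7 regions. Their means depend on that choice, and neither an excess nor a shortfall against them measures sharing beyond chance. Of the 567 regions of both uterine lines, 370 (65.3%, 61.2 to 69.2%) were also in a breast list, whereas of the 3597 regions of both breast lines 493 (13.7%, 12.6 to 14.9%) were in a uterine list. These counts and shares followed list length: with 1096 peaks from each list, 310 regions were in both breast lines alone, 388 in both uterine lines alone and 92 in all 4. At that length the breast lines shared 485 sites and the uterine lines 540, so the higher share of uterine regions found in the other tissue was not kept.

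**Figure D3:**
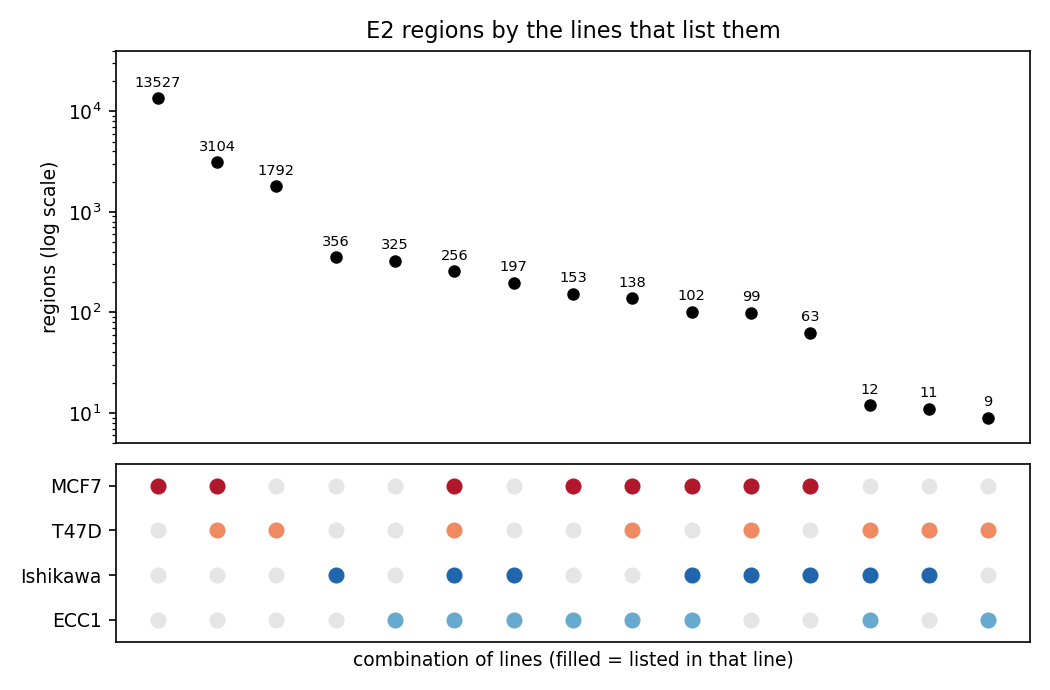
Number of E2 regions (log axis) for each combination of lines that list them, with filled circles below marking the lines. MCF7 alone held 13527 regions, both breast lines alone 3104, both uterine lines alone 197 and all 4 lines 256.

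The 8 regions of all 4 E2 lists with the highest mean percentile lay on chromosomes 1, 2, 3, 8, 13 and 15. The first was at 1q32.1 (chromosome 1, 200348752 to 200348757), with scores of 355 in MCF7, 174 in T47D, 52 in Ishikawa and 55 in ECC1, a mean percentile of 98.4. The region at 15q14 (chromosome 15, 37748142 to 37748149) had the scores 193, 188, 91 and 50 in the same order. A region at 2p25.1 (chromosome 2, 11556297 to 11556306) had 389, 257, 38 and 63, and this band holds GREB1, a textbook oestrogen-induced gene. A region at 8q22.1 (chromosome 8, 98845827 to 98845833) had 225, 69, 129 and 210, and the last was the highest score of the ECC1 list. The others lay at 2q11.2 (chromosome 2, 99619682 to 99619689), 1p36.22 (chromosome 1, 12583027 to 12583051), 3q26.32 (chromosome 3, 178154338 to 178154349) and 13q34 (chromosome 13, 113482121 to 113482137). Of the 8 regions, only 2q11.2 was in a uterine ethanol list, that of ECC1.

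Among regions of both breast lines and neither uterine line, 4 of the 5 with the highest MCF7 score lay within 20q13.2. They were at chromosome 20, positions 52173758 (571 in MCF7, 54 in T47D), 52199205 (417 and 11), 52245192 (475 and 41) and 52245447 (475 and 41). The last pair lay 255 bp apart and had equal scores in both lines. The other lay at 17q24.2 (chromosome 17, 62378955), with a score of 478 in MCF7 and 118 in T47D. All 5 were also in the MCF7 ethanol list.

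Among regions of both uterine lines and neither breast line, the highest ECC1 score was 75 at 11q24.3 (chromosome 11, 128300086), where Ishikawa had 60. The next lay at 19p13.3 (chromosome 19, 5845240), with 69 in ECC1 and 74 in Ishikawa, at 11q13.3 (chromosome 11, 69628397), with 58 and 37, at 2q37.1 (chromosome 2, 232948257), with 55 and 45, and at 17q25.3 (chromosome 17, 77987489), with 54 and 20. None of these 5 was in an ethanol list.

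Each E2 list also held high-scoring sites found in no other E2 list. For MCF7 the highest lay at 17q23.2 (chromosome 17, 57155567, score 392, and 56789048, score 341) and 20q13.31 (chromosome 20, 55271739, score 358), all above the 99th percentile of that list (99.84 to 99.95). For T47D they lay at 17q21.33 (chromosome 17, 46276777, score 252), 11q25 (chromosome 11, 132590813, score 128) and 1q41 (chromosome 1, 213640328, score 121). For Ishikawa they lay at 1q42.2 (chromosome 1, 231128324, score 31), 15q14 (chromosome 15, 37723861, score 29) and 4q22.1 (chromosome 4, 88258061, score 24), at percentiles 85.2 to 91.0. For ECC1 they lay at 5q35.1 (chromosome 5, 168660539, score 65), 17q21.2 (chromosome 17, 36456911, score 46) and 15q23 (chromosome 15, 68244877, score 40), at percentiles 93.9 to 98.8.

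The E2 lists also differed in their distribution over chromosomes (25151 peaks, chi-square 501, Cramér's V 0.0815, permutation p = 1e-05, the smallest possible). Each list was set against the other 3 together, which are mostly MCF7 peaks for every list but MCF7, and mostly T47D peaks for MCF7. The MCF7 and T47D results are thus largely the same contrast with opposite signs. T47D had a higher share on chromosome 11 (8.04% against 4.72%, odds ratio 1.77, Fisher's exact test, adjusted p = 2.86e-18) and on chromosome 3 (9.15% against 6.19%, odds ratio 1.53, adjusted p = 2.31e-12). It was also higher on chromosome 8 (6.16% against 5.12%, odds ratio 1.22) and lower on chromosome 2 (4.925% against 8.50%, odds ratio 0.558). MCF7 in turn was lower on chromosome 11 (4.55% against 7.45%, odds ratio 0.592, Fisher's exact test, adjusted p = 2.86e-18) and on chromosome 3 (5.93% against 8.85%, odds ratio 0.65, adjusted p = 3.13e-15). On chromosome 11 Ishikawa stood at 5.75% and ECC1 at 6.29%, between the breast lines, and on chromosome 3 Ishikawa stood at 9.49% (odds ratio 1.46, Fisher's exact test, adjusted p = 0.00454) and ECC1 at 6.88%. Ishikawa had a higher share on chromosome 12 (10.3% against 4.83%, odds ratio 2.27, Fisher's exact test, adjusted p = 7.32e-12), on chromosome 18 (2.65% against 1.31%, odds ratio 2.04) and on chromosome 4 (5.47% against 3.39%, odds ratio 1.65). MCF7 was higher on chromosome 2 (8.38% against 6.25%, odds ratio 1.37), chromosome X (1.96% against 1.45%, odds ratio 1.36) and chromosome 15 (3.46% against 2.78%, odds ratio 1.26). Chromosome 20 carried a lower share in Ishikawa (1.55%, odds ratio 0.409) and in ECC1 (1.85%, odds ratio 0.489). ECC1 was higher on no chromosome and lower on chromosomes 20 and X. The lower shares of MCF7, T47D and Ishikawa, and the uterine shares on chromosomes 3 and 11, lie outside the naming rule. They were chosen after their values were seen.

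Of 613 bands with at least 10 peaks, T47D was higher in 14 and lower in 5, MCF7 higher in 9 and lower in 20, Ishikawa higher in 10 and ECC1 higher in 8. Most bands higher in T47D, such as 11q14.3 and 11q23.2, were also among those lower in MCF7, so the 2 counts are not separate results. The bands with the highest odds ratios in T47D were 11q14.3 (11.85), 11q23.2 (8.21) and 11q24.2 (5.27). In Ishikawa they were 9p24.2 (12.0), 12p12.1 (9.95) and 8p11.23 (9.18), in ECC1 16p12.2 (7.57), 1p36.21 (5.655) and 8p21.3 (5.24), and in MCF7 15q21.2 (9.52), 2q33.1 (8.19) and 9q22.33 (7.75). The Ishikawa and ECC1 bands rested on 5 to 9 peaks each. Neighbouring peaks are not independent, and counting 1 Mb windows with a peak in place of peaks gave a Cramér's V of 0.0865.

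**Figure D4:**
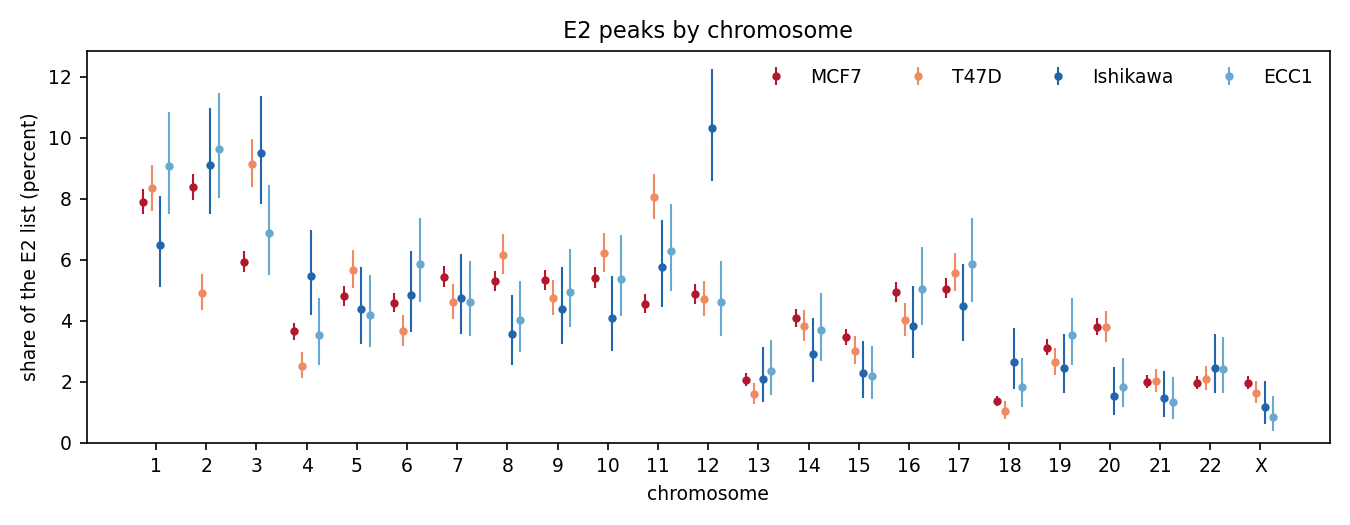
Share of each E2 list (percent) on each chromosome, with exact 95% intervals that cover counting only. Ishikawa stood at 10.3% on chromosome 12, and on chromosome 11 T47D stood at 8.04% and MCF7 at 4.55%.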

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

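The tests of MCF7 ethanol peaks also in uterine ethanol lists, of uterine top-100 sites without background-like sites and of extra DNA copies were written down before their results were seen; the tests of differences among the lines, the ratios from the lowest ethanol score or a common lowest score, and the tests of background-like sites as the whole cause, of low ethanol scores and of list length were chosen after the data were examined.

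The share of ethanol peaks also listed with E2 stood out because it differed among the 4 lines, at 91.2% in MCF7, 81.4% in T47D, 58.3% in Ishikawa and 58.8% in ECC1 (chi-square 229, permutation over peaks, p = 1e-05, the smallest possible). The ratio of E2 to ethanol peaks, counted from the lowest ethanol score, differed as well, at 8.83, 5.11, 3.37 and 4.12 in the same order (chi-square 238, permutation p = 1e-05, the smallest possible). That lowest score was 14 in the breast and 11 in the uterine lines, and from 14 in all lists the ratios were 8.83, 5.11, 4.67 and 5.46 (chi-square 126, permutation p = 1e-05, the smallest possible), with no difference detected among T47D, Ishikawa and ECC1 (chi-square 1.03, permutation p = 0.601). Both counts treat a score as the same in different lists, although its scaling is not stated. With 1 library per line and treatment, these p-values compare lists, and a difference between libraries would give the same.

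Uterine ethanol peaks were less often among the E2 peaks than breast ethanol peaks were. Sites near centromeres or common to all 4 ethanol lists were argued against as the whole cause, since without them the share was 51.0% in Ishikawa and 55.6% in ECC1. Whether background sites that give reads without receptor binding account for part of it was not decided. The 57 MCF7 ethanol peaks also in a uterine ethanol list stood at a median percentile of 60.6 in the MCF7 E2 list against 94.97 for the others. This difference of -34.4 points met the first sign written down. Their share listed with E2 was lower by 14.7 points only (77.2% against 91.9%), short of the 20 points written down as the other sign. In T47D the percentiles were 39.6 against 93.9 but the shares 76.9% and 81.8% (lower by 4.9 points, Fisher's exact test, p = 0.453). Both signs concern breast peaks, which does not tell why uterine ethanol peaks were missing from uterine E2 lists. Of the 24 regions of all 4 ethanol lists, 23 were in the Ishikawa E2 list and 19 in ECC1, so such common sites did not lower the uterine shares. Low ethanol scores as a cause remained undecided too, because the ethanol peaks from the median score up were listed with E2 at 77.7% in Ishikawa (68.8 to 85.0%) and 82.6% in ECC1 (74.1 to 89.2%), against 31.2% and 33.3% of those below it. The breast lines stood higher in both parts, at 98.5% and 83.1% in MCF7 and 96.9% and 64.8% in T47D, but their median scores of 21 and 19 lay farther above the lowest score of 14 than the uterine medians of 13 and 14 above 11, and with the E2 lists also limited to their peaks from the median score up the uterine shares were 56.2% and 58.7%, a setting that removes low-scoring E2 counterparts too. The E2 lists searched also differed in length, with 17442 peaks in MCF7, 5421 in T47D, 1096 in Ishikawa and 1192 in ECC1. A shorter E2 list can lack more counterparts of ethanol peaks, and its part in the lower uterine shares was not tested. Receptor binding without hormone that differs by tissue remains open and was not tested, as input libraries were not analysed here.

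E2 sites of one line were missing from the list of another. For the uterine sites missing from MCF7, too short an MCF7 list was argued against. At most 78 of the 100 highest uterine peaks (72 for Ishikawa) were in that list of 17442 peaks. Leaving out sites like background, those near centromeres or in every ethanol list, gave 71 for Ishikawa and 78 for ECC1. Sites near centromeres were thus argued against as the whole cause. Sites in every ethanol list were mostly in the MCF7 E2 list too (21 of 24), so leaving them out could hardly raise the numbers. Background sites particular to the uterine lists were not removed, so whether they contribute was not tested. For the MCF7 sites missing from T47D, too short a T47D list remained undecided: 88 of the 100 highest MCF7 peaks were in T47D (79.98 to 93.6%), and of the highest quintile of MCF7 peaks 52.9% were. Without sites like background, 26 Ishikawa and 20 ECC1 top-100 sites were in neither breast list, and of these 25 and 17 were in the other uterine list. Of all 100 highest peaks before that removal, 98 of Ishikawa and 87 of ECC1 were in the other uterine list. Sites missing from breast were thus not shared between the uterine lines more often than top sites in general. Positions had also been set jointly within each tissue. A tissue difference in site choice, which remains a hypothesis, and the joint processing of each tissue's lists thus cannot be told apart.

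Single lines had higher shares on some chromosomes and higher scores in some bands. Extra DNA copies of a chromosome in one line, or fewer in the other, may contribute but were not told apart from other causes. At sites shared with the other line of the tissue, the median rank shift towards the line with the higher share was positive in 13 of the 15 higher shares. In 4 of them it passed a permutation test after adjustment. These were MCF7 on chromosomes 2 (5.10 percentile points) and 15 (9.61) and T47D on chromosomes 3 (10.5) and 11 (7.65). The highest odds ratio, 2.27 for Ishikawa on chromosome 12, came with a shift of 1.94 points (permutation p = 0.85), and no Ishikawa shift passed. Higher shares and shifts came from the same E2 lists, so whatever raises scores on a chromosome can raise both. For the highest MCF7 scores, of which 25 of the top 100 lay in 20q13 or 17q22 to 17q25 against 5 in T47D, the shift over the whole bands was 3.09 points (permutation p = 0.0663). In the 12 windows of 1 Mb with those peaks the odds ratio of the lowest-scoring peaks, MCF7 against T47D, was 0.810 (0.514 to 1.28). Extra copies had been assumed to raise it, which was not checked, and the windows were picked by the MCF7 scores. As 44 shared sites there outside the top 100 shifted by 9.58 points, extra copies and stronger binding cannot be told apart without input libraries. A difference in chromatin between the lines remains open and was not tested.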

How the results depend on the processing

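Of 163 recomputed values, 98 stayed and 65 moved. A reversal could be recorded only for the Jaccard difference and for median score differences that passed the threshold, and 0 were recorded. Pairwise sharing within a tissue could not change with a distance of 100 bp, since its matched positions were identical. Breast ethanol numbers could not change with a lowest score of 14, which these lists already had. Peak numbers from the median score up were nearly bound to move. For the breast lines' ratios and shares, the lowest score of 14 and the lowest ethanol score are the same setting, counted again. The tally thus does not measure robustness. A count stayed when within 1.5 times its main value, a share or ratio when within its 95% interval, the mean log2 ratio and the Jaccard difference when within 1 SD, and a tested value when on the same side of 0.05. The last holds also for values never past the threshold, such as the median score difference of E2 peaks with and without an ethanol peak, which without background-like sites went from 2 to 1 in Ishikawa and from 0.5 to 0 in ECC1. The common lowest score of 14, the E2 peaks from the lowest ethanol score, the distance of 100 bp and the removal of background-like sites were chosen after the data were examined, and the former pair takes scores as comparable between lists. Results that passed a test kept their direction under the alternatives run on them, but numbers of peaks and regions followed list length, and at equal length more regions were in both uterine lines alone than in both breast lines alone, whereas the full lists gave the opposite order; the causes of the moves were not tested beyond that construction. With the peaks of each list from its median score up, the peaks numbered 659 (ethanol) and 9130 (E2) in MCF7, 288 and 2851 in T47D, 112 and 554 in Ishikawa and 109 and 671 in ECC1. Ethanol peaks shared with E2 then made up 97.6% in MCF7 and 94.1% in T47D, against 56.2% in Ishikawa and 58.7% in ECC1, the pairwise overlap of E2 lists was 74.6% for MCF7 and T47D, 54.7% for MCF7 and Ishikawa, 39.0% for T47D and Ishikawa and 58.8% for Ishikawa and ECC1, and 1855 regions were in both breast lines alone, 111 in both uterine lines alone and 136 in all 4. With a lowest score of 14 in all lists the E2 peaks numbered 11041 in MCF7, 2851 in T47D, 434 in Ishikawa and 595 in ECC1, and the ethanol peaks 93 in Ishikawa and 109 in ECC1. The overlap was then 78.6% for MCF7 and T47D, 57.8% for MCF7 and Ishikawa, 58.0% for MCF7 and ECC1, 39.4% for T47D and Ishikawa and 62.7% for Ishikawa and ECC1, with 2005, 86 and 114 regions in the 3 classes. The ratio to ethanol was 8.83 in MCF7, 5.11 in T47D and 4.67 in Ishikawa, and the share of ethanol peaks with an E2 peak 89.4%, 75.4%, 50.5% in Ishikawa and 50.5% in ECC1. With E2 peaks from the lowest ethanol score the ratio to ethanol was 8.83 in MCF7, 5.11 in T47D, 3.37 in Ishikawa and 4.12 in ECC1, the mean log2 ratio 2.32, and the share of ethanol peaks with an E2 peak 89.4%, 75.4%, 39.1% and 46.0%. Without background-like sites the ratio was 6.69 in Ishikawa and 7.11 in ECC1, and the Ishikawa share 51.0%. At equal length the overlap was 44.3% for MCF7 and T47D, 16.3% for MCF7 and Ishikawa, 18.6% for MCF7 and ECC1, 16.1% for T47D and Ishikawa and 15.9% for T47D and ECC1, with 310, 388 and 92 regions in the 3 classes. Taking the upper 50% of the shortest list as the equal length raised the difference between within-tissue and between-tissue Jaccard indices from 0.214 to 0.243. Leaving out each line in turn gave 3203 (without Ishikawa) to 16631 (without T47D) regions in breast alone, with 4896 without MCF7, 209 (without T47D) to 553 (without ECC1) in uterus alone, with 299 without MCF7 and 522 without Ishikawa, and 268 (without MCF7) to 394 (without Ishikawa) in all remaining lines. Without T47D and Ishikawa, the lines with contradictory labels, the mean log2 ratio of E2 to ethanol was 3.15, and leaving out each line gave 2.76 to 3.199. E2 was compared with ethanol within each line, so these ratios are paired by line. A reciprocal overlap of 50%, thresholds on fold or FDR, strength by p-value or width, distances to genes, motifs and gene lists were not run, since the lists hold points with 1 score and hg18 annotation and sequence were not used here. Unknown depth limits what absence from a list can show: a site missing from a short list was not detected at that list's threshold, which does not make it unbound.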

Other observations

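The values and tests of this part were all chosen after the data were examined. Counting ERα peaks in windows of 1 Mb, the densest E2 window was the same in both breast lines, at 16q24.1 (chromosome 16, 84000000 to 84999999), with 58 peaks in MCF7 and 26 in T47D, against 0 in Ishikawa and 1 in ECC1. A window at 20q13.13 (chromosome 20, 48000000 to 48999999) held 56 MCF7 and 23 T47D peaks and 5 and 2 in the uterine lines. The densest Ishikawa window, at 12q24.31 (chromosome 12, 123000000 to 123999999), held 12 peaks and had 48 in MCF7, 16 in T47D and 8 in ECC1. The densest ECC1 window, at 10q22.3 (chromosome 10, 80000000 to 80999999), held 13 peaks and had 36 in MCF7, 14 in T47D and 3 in Ishikawa. These are raw counts from E2 lists of 17442 (MCF7), 5421 (T47D), 1096 (Ishikawa) and 1192 (ECC1) peaks. They do not show in which line a window was denser relative to its list.

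Over all 8 lists there were 20429 regions, of which 13 were in every list. Both breast ethanol lists and neither uterine one held 290 regions, and both uterine ethanol lists and neither breast one held 44. The 24 regions of all 4 ethanol lists did not stand at the top of the E2 lists: 21 were in the MCF7 list at a median percentile of 63.9, 20 in T47D at 42.2, 23 in Ishikawa at 69.5 and 19 in ECC1 at 65.7.

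Positions matched between tissues were more often identical in ethanol lists, at 64 of 182 matches (35.2%), than in E2 lists, at 160 of 1962 (8.15%; odds ratio 6.11, Fisher's exact test, p = 1.53e-21). Matches were summed over 4 pairs of lists that share members, so 1 site can count up to 4 times. The test takes these repeats as independent, which makes its p-value too small. Peaks within 2 Mb of a centromere made up 14.7% of the ECC1 ethanol list against 1.87% of the E2 peaks without an ethanol counterpart (odds ratio 9.02, Fisher's exact test, adjusted p = 1.17e-12), and 9.90% against 3.86% in Ishikawa (odds ratio 2.73, adjusted p = 0.002615). In MCF7 the shares were 3.6% and 2.17% (odds ratio 1.69, Fisher's exact test, adjusted p = 0.00279), and in T47D 3.23% and 2.17% (odds ratio 1.5, adjusted p = 0.132).

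In the MCF7 E2 list 4 neighbouring pairs of peaks lay within 300 bp of each other, and all 4 pairs carried equal scores, as did 4 of 4 such pairs in T47D. Ishikawa and ECC1 had 1 such pair each, with unequal scores. Over neighbours within 1 kb, 41 of 670 pairs in MCF7, 18 of 191 in T47D, 1 of 19 in Ishikawa and 0 of 22 in ECC1 had equal scores.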
